A study of Saccharomyces cerevisiae with 25 samples.

How the data were processed

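RNA was measured in 25 libraries of Saccharomyces cerevisiae BY4741 carrying a PHO84 promoter reporter and a DAmP allele of PHO85, 1 from high phosphate medium at 0 min and 24 taken every 15 min during 360 min in medium without phosphate. Per the labels, RNA was extracted from lyticase-treated cells in plates with a NucleoSpin 96 kit, copied to cDNA for each sample and sequenced on an Illumina HiSeq instrument. The submitters' processing notes name Bowtie as the aligner and R64 as the genome build, while the counter and all versions are not given in the sources used here. Whether reads were assigned by strand is not stated either, so overlapping and antisense genes may share reads. The deposited values are log2 reads per 1000000 (RPM), made by the authors by leaving out genes with fewer than 10 reads in a library and scaling the remaining genes of that library, as the values themselves show. In every column the values on the linear scale sum to 1000000, and the lowest value is shared by several genes and fits 10 reads. With that value set to 10 reads, 70.7% to 95.3% of the values of a library, and at least 93.4% in each deeper library, were whole reads within 0.01. The labels speak of a normalization to the first time point, but the columns hold levels, including a column for 0 min, and no such subtraction was found.

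The table had 6701 rows. Of these, 51 had no gene name and no value, 6650 had a name, and 5962 matched the R64 annotation used for positions, which may be another release than the one the submitters used. The other 688 named rows were kept without a position, and 2 rows share a symbol. No value at all was given for 981 genes, 26 genes had a value in every library and 2475 in all 20 deeper libraries. Symbols follow the deposited table, so HOR2 is the gene now called GPP2 and MET17 that also called MET15. Listed reads per library ran from 766.5 to 4954493, and a library under 100000 listed reads was called shallow, a limit chosen after seeing the data. With so few reads the lowest value that can be listed is high, so the mean of a gene in a window rests on the libraries that list it.

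Each time point is 1 library, so windows of 8 consecutive libraries stood in for replicates: early (15 to 120 min), middle (135 to 240 min) and late (255 to 360 min), with 0 min as a group of 1 assumed to vary like the others. The windows, the gene lists, the tests and the rule for naming genes were chosen before the data were examined. The filter required a mean of at least 10 RPM over the 25 libraries with unlisted values as 0, which 4809 genes met, and a value at 0 min and in at least 4 libraries of each window, which left 4364 genes. The plan had asked for no missing value in units other than counts or RPM, which only 26 genes meet, so the rule for RPM was used with the second condition added after seeing the data. The plan's branches for counts and for a pseudocount did not apply, because the values are already log2.

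Genes were tested with limma 3.58.1 in R 4.3.3. A linear model per gene used the libraries with a value, and variances were moderated by empirical Bayes with a trend on mean level and robust settings, with unlisted values left out. Because 4338 of the tested genes lack a value somewhere, the model was fitted gene by gene with limma's variance moderation. On the 2475 complete genes of the deeper libraries it was checked against the standard limma functions, with 1355 calls from both. One model gave the contrasts of the windows with each other and with 0 min, and a second gave an F test of a natural cubic spline of time with 4 degrees of freedom, with a separate coefficient for 0 min. P-values were adjusted over all tested genes by Benjamini-Hochberg with a threshold of 0.05, and also within each list where a count adjusted over the list alone is given. The direction of a spline call is the sign of late minus early.

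Of 29 lists fixed from general knowledge, which included markers of both mating types and of meiosis, 27 had the 3 tested genes required for camera. Camera was run with a preset correlation of 0.01 and with an estimated correlation, and fry on the genes complete in the deeper libraries. The correlation was estimated from residuals around the window means, and was 0.914 for ribosomal proteins. A change that the genes of a list share within a window therefore raises it. Fry tests a list against no change, not against other genes, and its values are not used for calls. The share of listed reads taken by a list has an exact Clopper-Pearson interval of 95%, which covers counting error only. The order of induction was estimated from a natural cubic spline with 6 degrees of freedom over all libraries, as the first minute at which the curve passes the midpoint between its 0 min value and its maximum, with 1000 residual bootstraps. The median autocorrelation of spline residuals between neighbouring times was -0.204. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.

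Genes were named by rule: all PHO regulon and signalling genes that passed, with PHO84, PHO85, PHO80, PHO81, PHO4, PHO2, SPL2 and PHO5 always given; the 10 largest rises and falls per contrast among genes that passed and have a symbol; 2 to 4 members with the smallest adjusted p of each other list; and the deleted markers and mating type genes. A few list members beyond the rule's number were named after their values were seen, those that were exceptions in a list or its only other calls.

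The tests were tested on simulated data, in 5 runs with 200 changed genes each, in which reads were drawn at the depth of each library around the mean level of each gene, with its fitted spread, and passed through the 10 read minimum. Between the late and early windows 42.3% of genes changed 2-fold and 98% of genes changed 4-fold were called, against 0.0916% of unchanged genes. For the late window against 0 min these were 2.2%, 57.4% and 0.0137%, and for the spline 22.9%, 89.8% and 0.115%. A raised list was called in 5 of 5 runs. The simulated genes vary independently of each other, so these runs do not show how often a list is called by chance. Simulated rises with a midpoint at 20 min were placed at 30.2 min with an interval that never held the true value, while for later midpoints 82% to 100% of intervals held it. The times were also reassigned among the 24 libraries without phosphate, 100 assignments with the labelled one included.

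The alternatives set before the data were examined were quantile normalization, no filter, a filter at 50 RPM, empirical Bayes without trend, limma arrayWeights, only odd-numbered or even-numbered time points, splines with 3 or 6 degrees of freedom, leaving out each library in turn, the spread around the spline, an estimated correlation, and midpoints on the linear scale or from a spline with 8 degrees of freedom. Added after seeing the data were leaving out the 5 shallow libraries, and with the remaining 20 also centring on medians, setting unlisted values at 5 reads, keeping only genes complete in them, and scaling to reads outside ribosomal protein genes. PHO85 was listed too rarely to be tested, and HIS3, LEU2, MET17 and URA3 had no values.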

Results

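Transcript levels were followed by RNA sequencing in Saccharomyces cerevisiae cells moved from high phosphate medium to medium without phosphate. One time course gave 25 libraries, 1 from the high phosphate medium at 0 min and 24 from the medium without phosphate, taken every 15 min from 15 to 360 min. The cells were a derivative of BY4741, a haploid laboratory strain of mating type a that lacks HIS3, LEU2, MET17 (also called MET15) and URA3. They carried a yellow fluorescent protein gene under the PHO84 promoter and a DAmP allele of PHO85, a change behind the stop codon that lowers the stability of the messenger RNA. Pho85 is the kinase that, with the cyclin Pho80, holds the transcription factor Pho4 inactive while phosphate is plentiful. The 24 libraries without phosphate were compared as an early window (15 to 120 min), a middle window (135 to 240 min) and a late window (255 to 360 min) of 8 libraries each. No time point was replicated and no strain with an intact PHO85 was analysed here, so p-values measure only the spread between these libraries. Confidence intervals of read shares cover counting error only, and bootstrap intervals of induction times cover only the spread of the libraries around a fitted curve.

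Depth differed widely between the libraries. Taking the lowest listed value of each library as 10 reads, the 0 min library held 4954493 reads in 5589 listed genes, and the libraries without phosphate held between 766.5 reads in 29 genes at 210 min and 1981423 reads at 105 min. Levels are given as RPM, reads per 1000000 reads of listed genes. Of all libraries, 5 held fewer than 100000 listed reads and are called shallow here, a limit set after the depths were seen. These were the libraries at 45 min (18553 reads, 601 genes), 75 min (81208 reads, 1693 genes), 90 min (4959 reads, 205 genes), 210 min and 330 min (29748 reads, 920 genes). The other 19 libraries without phosphate held 169769 to 1981423 reads, with a median of 603361. A gene with fewer than 10 reads has no value in that library, so a gene missing from a library lay below 2.02 RPM at 0 min, but anywhere below 539 RPM at 45 min.

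**Figure D1:**
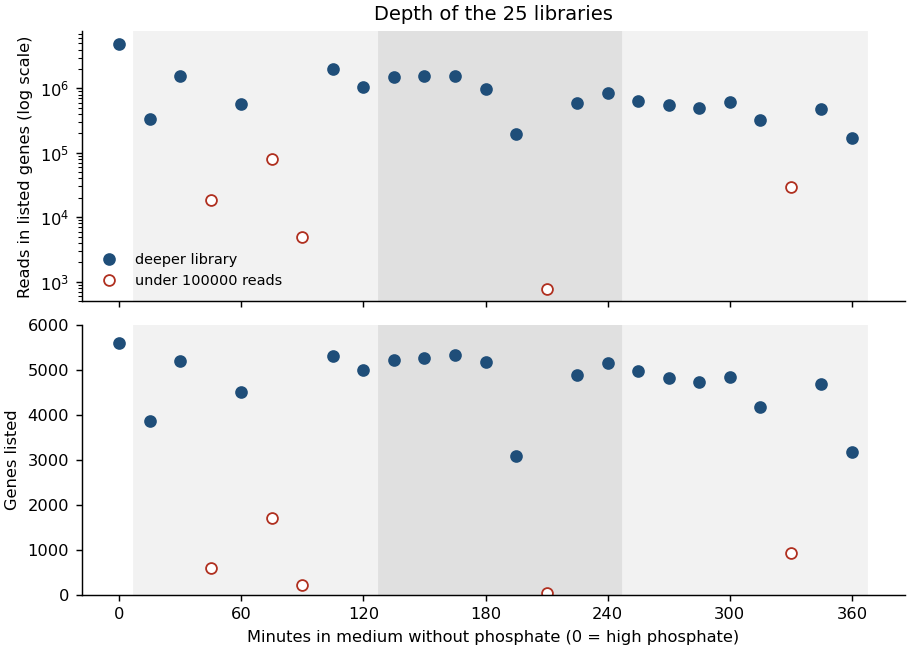
Reads in listed genes (upper panel, log scale) and number of listed genes (lower panel) for each of the 25 libraries, plotted against minutes in medium without phosphate, with open circles for the 5 libraries under 100000 reads. Shading marks the early, middle and late windows, and the libraries at 45, 75, 90, 210 and 330 min lie below all others in both panels.

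PHO85 itself was listed in 4 of the 25 libraries, at 5.65 RPM at 0 min (28 reads), 5.05 at 105 min (10 reads), 6.46 at 165 min (10 reads) and 21.3 at 240 min (18 reads). It was too rarely listed to be tested, and no comparison with an intact allele could be made. The genes deleted in BY4741, HIS3, LEU2, MET17 and URA3, had no listed value in any of the 25 libraries. Of the genes that mark mating type a, MFA1 and MFA2, which encode a-factor, were each listed in 24 libraries and the alpha-factor receptor gene STE2 in 23, with AGA2 in 20, BAR1 in 19, STE6 in 18 and ASG7 in 15. Of the alpha-specific genes STE3 was listed in 17 libraries, SAG1 in 15 and MF(ALPHA)1 in 3 with at most 21 reads, while MF(ALPHA)2 was listed in none.

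The early window was set against the 0 min library to ask which transcripts change first after the transfer to medium without phosphate. No library came from cells transferred to high phosphate medium. In every contrast with 0 min, loss of phosphate therefore cannot be told apart from handling and the change of medium. SPL2 (chromosome VIII, 374654 to 375100 in build R64), a regulator of low-affinity phosphate uptake, rose most, by 13.5-fold (log2 change 3.75, SE 0.44, 7 libraries against 1; limma, adjusted p = 1.21e-05), from 5.41 to 9.16 ± 0.54 (SD, n = 7) log2 RPM. PHO84 (XIII, 24037 to 25800), the high-affinity phosphate transporter gene, rose 10.2-fold (log2 change 3.35, SE 0.53; limma, adjusted p = 0.00103). Also higher were 3 subunit genes of the vacuolar polyphosphate polymerase, VTC3 by 6.59-fold, VTC1 by 4.75-fold and VTC4 by 4.50-fold. The acid phosphatase genes PHO12 and PHO11 rose 12.8-fold and 10.2-fold, though they are near-identical copies whose reads the counting could have split between them, and the log2 change of PHO11 was 2.73 without the shallow libraries. In all, 7 of the 19 tested members of the PHO regulon, the set of Pho4 targets, were higher in the early window, and 15 of 19 adjusted over the list alone. PHO89 (II, 796798 to 798522), a sodium-coupled phosphate transporter gene, had a log2 change of 3.38 (SE 0.80; limma, adjusted p = 0.0974), and the acid phosphatase gene PHO5 (II, 429548 to 430951) one of 2.97 (SE 1.06; limma, adjusted p = 1), both with wide spread across the early libraries. These 2 log2 changes were 2.80 for PHO89 and 1.99 for PHO5 without the shallow libraries.

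Outside the PHO regulon, FMP43, a mitochondrial pyruvate carrier subunit gene, rose 7.12-fold and NCE103, the carbonic anhydrase gene, rose 4.98-fold, and 1 gene with only a systematic name rose too. That made 10 genes higher and 0 lower among 4364 tested with limma, against 132 with an unadjusted p under 0.05 in either direction. The regulators of the pathway did not pass the test. The log2 change was 1.48 for PHO81 (VII, 954674 to 958210), the inhibitor of the Pho80-Pho85 kinase (SE 0.37; limma, adjusted p = 0.124), 0.32 for PHO80 (XV, 325249 to 326130), -0.25 for PHO4 (VI, 225020 to 225958) and -0.22 for PHO2 (IV, 270222 to 271901), whose product partners Pho4. None of the other lists had a called member, and adjusted over the list alone 1 of 12 TCA cycle genes, PYC1, was higher. The median log2 changes were 1.52 over 33 general stress response genes, -0.15 over 136 cytosolic ribosomal protein genes and -0.80 over 37 ribosome biogenesis genes. Leaving out the 5 shallow libraries gave 10 genes again, all 10 shared, but quantile normalization left 0 with limma, the even-numbered time points 1 and the odd-numbered ones 4. Here and below, quantile normalization covered all libraries and spreads the few listed genes of a shallow library over the whole range. What it changes may therefore come from those libraries and not from the scaling.

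**Figure D2:**
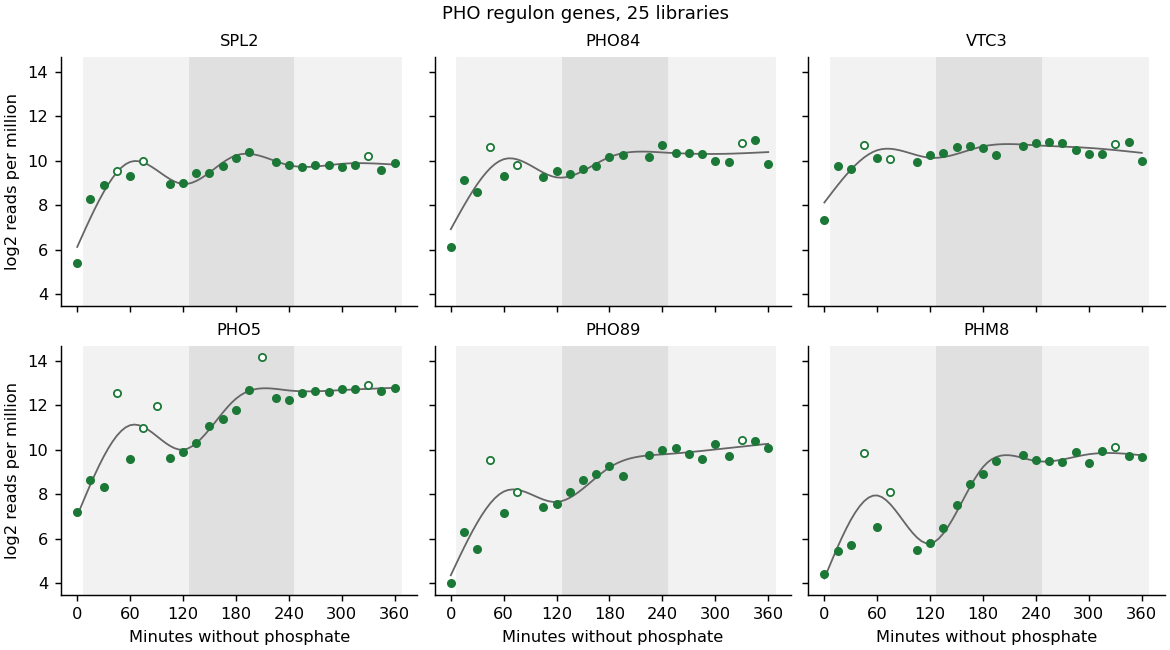
Log2 RPM of SPL2, PHO84, VTC3, PHO5, PHO89 and PHM8 in each library against minutes without phosphate, with open circles for the 5 shallow libraries and the fitted spline as a line. SPL2, PHO84 and VTC3 were already far above their 0 min values at 15 min, while PHO5, PHO89 and PHM8 were higher in the late window than in the deeper early libraries.

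The middle and late windows were set against 0 min to ask how far the response went. In the middle window PHO89 was 33.8-fold above its 0 min level (log2 change 5.08, SE 0.80, 7 libraries against 1; limma, adjusted p = 5.98e-04), PHO12 29.8-fold, PHO5 27.2-fold, PHO11 23.6-fold, SPL2 22.0-fold and PHO84 15.0-fold. PHM6, a gene of unknown function, rose 17.4-fold. Genes outside the regulon joined them, among them GLC3, the glycogen branching enzyme gene (20.7-fold), HXK1, a hexokinase gene (17.2-fold), and UGX2 (14.1-fold). PHO81 also rose, 3.70-fold (limma, adjusted p = 0.0046). Of the PHO regulon 14 of 19 members were called, all higher, and 17 of 19 adjusted over the list alone. PHO80 (log2 change 0.67), PHO4 (0.13) and PHO2 (0.56) did not pass. Of 33 stress response genes 10 were higher (29 adjusted over the list alone), among them HSP104, PNC1, HSP42 and GAD1. So were 3 of 13 autophagy and vacuolar protease genes (8 adjusted over the list alone), ATG19, ATG7 and ATG9, and 1 of 6 nitrogen catabolite repression genes (3 adjusted over the list alone), the urea transporter gene DUR3. No other list had a called member with limma. Adjusted over the list alone, 29 of 37 ribosome biogenesis and 2 of 9 iron genes were lower, and 3 of 12 TCA cycle, 2 of 17 methionine, 1 of 7 zinc, 1 of 3 meiosis genes and the alpha-specific STE3 were higher. In all 77 genes were higher and 0 lower with limma, 874 having an unadjusted p under 0.05 in either direction. The median log2 change was nevertheless -1.50 over 136 ribosomal protein genes and -1.53 over 37 ribosome biogenesis genes. Change within a window counts as spread, and the ribosomal protein share fell within this one, as described below. That no gene was called lower does not show that none had fallen. Without the 5 shallow libraries 148 genes were called, 142 higher and 6 lower, 75 of them shared with the 77, whereas limma with arrayWeights called 48, the odd-numbered time points 11 and quantile normalization 0. Median centring of the deeper libraries left 6 stress response genes, 1 autophagy gene and 0 nitrogen catabolite repression genes higher with limma, so that the DUR3 call was lost.

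In the late window CTT1 (VII, 654634 to 656322), the cytosolic catalase gene, was 70.4-fold above 0 min (log2 change 6.14, SE 1.24, 8 libraries against 1; limma, adjusted p = 0.0033). PHO89 followed at 66.5-fold, then MSC1 (59.8-fold), GRE1 (57.0-fold), GLC3 (46.9-fold), PHO5 (44.5-fold), GPG1 (44.3-fold), FMP16 and HSP12, a membrane chaperone gene (both 43.4-fold), and SIP18 (43.2-fold). All 10 genes with the largest falls encoded ribosomal proteins, led by RPL8A (VIII, 35255 to 36025) at a log2 change of -4.12 (SE 1.09; limma, adjusted p = 0.0137), RPL12A at -3.72 and RPL16B at -3.68, with RPS26B, RPL33B, RPL9A, RPS11A, RPS24B, RPS8B and RPS22A between -3.68 and -3.43. PHO84 was 18.5-fold, SPL2 21.5-fold and PHO81 5.37-fold higher, whereas the log2 changes of PHO80 (0.96), PHO4 (0.30) and PHO2 (0.97) did not pass. Of the PHO regulon 18 of 19 members rose, and 19 adjusted over the list alone. The exception was KCS1, an inositol phosphate kinase gene, at a log2 change of 2.31 (limma, adjusted p = 0.0605). In all 849 genes were called, 659 higher and 190 lower, and the median of all genes lay 0.48 above 0 on the log2 scale.

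The split between higher and lower calls moved with the scaling. With the 20 deeper libraries centred on their medians the late window differed from 0 min for 806 genes, 365 higher and 441 lower, and scaled to the reads outside ribosomal protein genes it differed for 755, 374 higher and 381 lower. The single 0 min library was assumed to vary like the libraries of a window, and quantile normalization left only 22 calls.

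By list, with the count adjusted over the list alone in parentheses, the late window against 0 min showed 125 (134) of 136 ribosomal protein and 8 (9) of 37 ribosome biogenesis genes lower, the latter including NOP1, RPA135 and UTP20. Higher were 31 (32) of 33 stress response, 14 (21) of 30 respiratory chain, 7 (9) of 12 TCA cycle, 10 (12) of 13 autophagy and vacuolar protease, 5 (5) of 6 nitrogen catabolite repression and 5 (9) of 16 G2/M genes. Examples are HSP104 at a log2 change of 3.87, SDH4 at 1.91, LSC2 at 1.99, ATG19 at 3.34 and DUR3 at 3.65. Others named by the same rule are GAD1, ATP17, CIT1, ATG7, GAP1, CLB1 and ALK1. Smaller numbers rose among M/G1 (3 (3) of 15, DSE4, PIR1 and SIC1), Gcn4 target (5 (5) of 27, among them ARG4 and LYS1) and zinc genes (2 (2) of 7, ZAP1 and DPP1). The same holds for cell wall integrity (2 (2) of 12, SED1 and PST1) and glycolysis genes (2 (2) of 16, ENO1 and TDH1). Over all tested genes 659 of 4364 were higher, so counts near that share do not set a list apart. PCL9, which encodes a Pho85 cyclin, and NDT80, a meiotic regulator, were each the only called member of their lists, with 1 adjusted over the list alone in both. Members went both ways among methionine genes, 5 higher and 2 lower of 17 (9 and 3 adjusted over the list alone), with SAM1 at -2.27 and MET16 at 1.89. The same was seen for purine and one-carbon genes, 7 and 1 of 20 (9 and 1), GCV1 and HIS4 being higher, and for Hsf1 chaperones, HSP82 higher and SSA2 lower of 18 (1 and 0). FET3, an iron oxidase gene, was the only iron regulon gene called, lower. No member was called among PHO signalling, hexose transporter, G1/S, histone, phospholipid, a-specific or haploid-specific genes, with limma, nor adjusted over the list alone. The alpha-specific STE3 had a log2 change of 1.05 and passed only over its list of 1. With the deeper libraries centred on their medians, the median changes of the Hsf1, hexose transporter, G1/S, histone, Gcn4, a-specific, haploid-specific and cell wall integrity lists became negative. With quantile normalization those of the PHO signalling, Pho85 cyclin, Hsf1, hexose transporter, G1/S, M/G1, Gcn4, methionine, purine, zinc, a-specific, alpha-specific, haploid-specific and meiosis lists did. Quantile normalization left 4 PHO regulon and 6 stress response genes higher, 2 ribosomal protein genes and 1 ribosome biogenesis gene lower, and no call in any other list. Median centring of the deeper libraries gave 22 ribosome biogenesis genes lower, and 3 TCA cycle, 2 G2/M, 1 M/G1, 3 nitrogen catabolite repression and 1 zinc gene higher. It gave 3 higher and 4 lower Gcn4 targets, 1 and 4 methionine, 3 and 1 purine, 2 and 4 Hsf1, 0 and 2 PHO signalling and 0 and 0 Pho85 cyclin genes. Leaving out the shallow libraries, without centring, gave 4 higher and 1 lower Hsf1 and 4 and 1 glycolysis genes, 4 cell wall integrity and 20 respiratory chain genes higher and 2 iron genes lower. It also called 1 PHO signalling, 1 histone and 1 haploid-specific gene higher.

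Camera with a preset correlation called 9 of 27 lists in the late window against 0 min, 7 higher and 2 lower. These were the PHO regulon, stress response, respiratory chain, TCA cycle, G2/M, autophagy and nitrogen catabolite repression lists, and the ribosomal protein and ribosome biogenesis lists. Only the PHO regulon kept its call, at adjusted p = 0.0494 with an estimated correlation. The values were adjusted p = 0.0886 with an estimated correlation for ribosomal proteins, 0.331 for ribosome biogenesis, 0.401 for stress response, 0.526 for the respiratory chain, 0.579 for the TCA cycle and for nitrogen catabolite repression, 0.621 for G2/M and 0.407 for autophagy genes. Camera with the preset correlation called these 9 lists and the iron regulon, lower at adjusted p = 0.0468, when the shallow libraries were left out. With an estimated correlation the iron regulon lost that call (camera, adjusted p = 0.376), and only the PHO regulon kept its call (camera, adjusted p = 0.00721).

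Against the early window, the late window asks what changed while phosphate remained absent. CTT1 rose 25.3-fold (log2 change 4.66, SE 0.72, 8 libraries against 4; limma, adjusted p = 5.42e-05), and the other genes with the largest rises were GPG1 (18.0-fold), GRE1 (17.9-fold), SPG4 (17.6-fold), FMP16 (15.9-fold), DDR2 (15.4-fold), ALD3 (14.5-fold), SIP18 (14.5-fold), GND2 (13.4-fold) and MSC1 (log2 change 3.58). Without the shallow libraries the log2 changes of GRE1, SIP18 and MSC1 were 5.10, 4.69 and 4.22. GRE1 and SIP18 encode hydrophilins induced by drying and osmotic stress, SPG4 is linked to survival in stationary phase, and ALD3 and GND2 encode an aldehyde dehydrogenase and a dehydrogenase of the pentose phosphate pathway. All 10 of the largest falls were again of ribosomal protein genes. RPL8A fell by 4.01 on the log2 scale (SE 0.57, 7 libraries against 6; limma, adjusted p = 1.99e-05), from 9.26 ± 0.13 (SD, n = 6) to 5.25 ± 0.83 (SD, n = 7), and RPL9A, RPL27A, RPS8B, RPL33B, RPS26B, RPS22A, RPS9A, RPL12A and RPS11A had log2 changes from -3.64 to -3.19. The late mean of RPL8A includes 6.95 at 360 min, a library in which no value below 5.88 could be listed. Many of these genes have a close paralog, so their single values are uncertain where reads were shared.

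The ribosomal protein list fell almost as a block. Its log2 changes were lower for 135 of 136 genes, also adjusted over the list alone, with a median of -2.68, and only RPL15B (log2 change 0.36; limma, adjusted p = 0.186) was not called, while quantile normalization left 81 genes lower. Together these genes took 33.7% of all listed reads at 0 min (95% Clopper-Pearson interval 33.7 to 33.8%) and 31.2% ± 1.54 (SD, n = 5) in the deeper early libraries. The share was 28.5% at 150 min, 23.3% at 165 min, 14.2% at 180 min and 5.01% at 225 min, and it averaged 5.02% ± 1.16 (SD, n = 7) in the deeper late libraries. The shallow libraries at 330 min, with 16.1% (15.7 to 16.6%), and at 90 min, with 45.4% (44.0 to 46.8%), stood apart. A deeper neighbour reduced by simulation to the 90 min depth gave a ribosomal protein share of 57.0% to 61.1%, so the 90 min share was not raised beyond what depth gives. The general stress response list moved the opposite way, with 31 of 33 genes higher (32 adjusted over the list alone), a median log2 change of 2.07, and examples in DDR2 (3.94), GAD1 (3.19), HSP104 (1.84) and DCS2 (2.89). Its share of reads was 0.180% at 0 min, 0.452% ± 0.111 (SD, n = 5) in the deeper early libraries and 3.44% ± 0.543 (SD, n = 7) in the deeper late ones, the shallow 45 and 210 min libraries standing apart at 1.80% and 7.30%. Camera with a preset correlation called both lists, and the ribosomal proteins kept the call at adjusted p = 0.016 with an estimated correlation. The stress response list did not, at adjusted p = 0.457 with an estimated correlation.

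**Figure D3:**
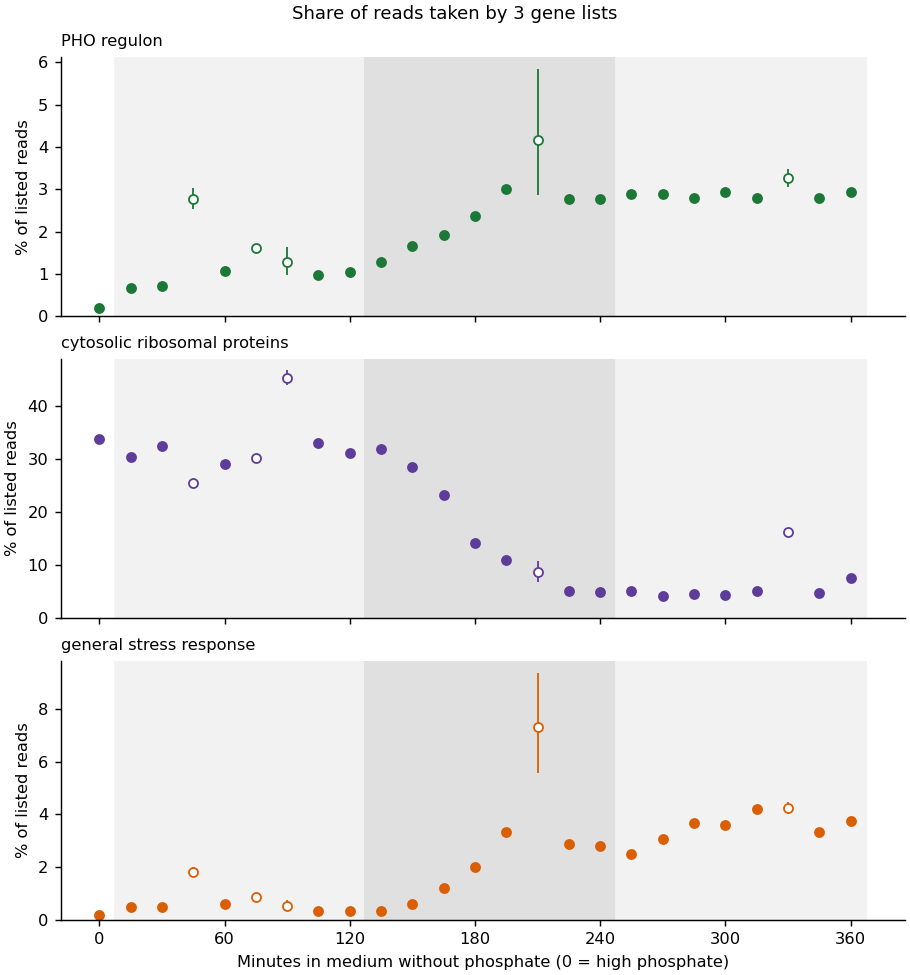
Percent of listed reads taken by the PHO regulon (top), cytosolic ribosomal protein (middle) and general stress response (bottom) lists in each library against minutes without phosphate, with 95% Clopper-Pearson intervals, open circles for the 5 shallow libraries and shading for the windows. The ribosomal protein share passes from 33.7% at 0 min through 14.2% at 180 min to 5.01% at 225 min, while the stress response share passes from 0.180% to 2.86% over the same times.

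Within the PHO regulon, PHM8, a nucleotidase gene, rose 8.04-fold from the early to the late window (log2 change 3.01, SE 0.56; limma, adjusted p = 2.48e-04), PHO89 6.39-fold, PHO5 5.68-fold and PHM6 4.48-fold. Without the shallow libraries the log2 changes were larger, 3.85 (SE 0.44) for PHM8, 3.46 (SE 0.32) for PHO5 and 2.77 (SE 0.27) for PHM6. PHO84 and SPL2, which were already high in the early window, rose 1.82-fold and 1.60-fold, and PHO81 rose 1.92-fold. VTC3 had a log2 change of 0.48 (limma, adjusted p = 0.0615), and the other 18 of 19 members were called, 19 adjusted over the list alone. The share of reads taken by the regulon was 0.198% at 0 min, 0.890% ± 0.185 (SD, n = 5) in the deeper early, 2.25% ± 0.648 (SD, n = 7) in the deeper middle and 2.86% ± 0.0659 (SD, n = 7) in the deeper late libraries. Camera called the list higher with a preset correlation, and gave adjusted p = 0.457 with an estimated correlation. In the PHO signalling list PHO2 rose 2.29-fold (limma, adjusted p = 0.00316) and PHO3, an acid phosphatase gene made in high phosphate, fell by 1.61 on the log2 scale (limma, adjusted p = 6.81e-04). PHO80 (log2 change 0.64) and PHO4 (0.54) were among the 7 of 9 members not called, and 1 higher and 1 lower were also called adjusted over the list alone. The PHO2 call was lost with quantile normalization, which gave 0 higher and 2 lower in this list, and median centring of the deeper libraries gave 1 higher and 3 lower.

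Respiratory chain and ATP synthase genes rose in 23 of 30 cases (26 adjusted over the list alone), with SDH4 at a log2 change of 1.95, CYT1 at 1.43 and ATP17 at 1.25. TCA cycle genes rose in 6 of 12 (6 adjusted over the list alone), with LSC2 at 1.45 and MDH1 at 1.22. Autophagy and vacuolar protease genes rose in 12 of 13 cases (12 adjusted over the list alone), among them ATG19 at 2.32 and the protease inhibitor gene PAI3 at 3.20. Of 6 nitrogen catabolite repression genes 5 rose (5 adjusted over the list alone), among them the general amino acid permease gene GAP1 at 2.67 (3.38 without the shallow libraries) and DUR3 at 2.23. G2/M genes rose in 11 of 16 cases (12 adjusted over the list alone), led by the cyclin gene CLB1 at 1.66 and by SWI5, a transcription factor gene, at 1.12, and M/G1 genes rose in 8 of 15 (11 adjusted over the list alone), led by the cell wall genes PIR1 at 1.36 and DSE4 at 1.16 and by SIC1, a Cdk inhibitor gene, at 1.19. Ribosome biogenesis genes fell in 11 of 37 cases (11 adjusted over the list alone), with RPA135, an RNA polymerase I subunit gene, at -1.45 and UTP20 at -0.94, and Hsf1 chaperone genes in 5 of 18 (5 adjusted over the list alone), with SSA2 at -1.25 and HSP60 at -0.68. Camera with a preset correlation called these 8 lists, in the directions given, but without the shallow libraries the TCA cycle list lost its call (camera, adjusted p = 0.0617). None kept the call, at adjusted p = 0.457 with an estimated correlation for the respiratory chain, autophagy, nitrogen catabolite repression, M/G1, ribosome biogenesis and Hsf1 lists, 0.592 for the TCA cycle and 0.499 for G2/M. Since change shared within a window enters that correlation, a lost call does not show that a list was unchanged. The counts also moved with the scaling. Median centring of the deeper libraries and quantile normalization of all libraries gave, in this order, 19 and 9 respiratory chain, 6 and 0 TCA cycle, 12 and 10 autophagy, 5 and 4 nitrogen catabolite repression, 6 and 2 G2/M and 5 and 0 M/G1 genes higher. They gave 19 and 10 ribosome biogenesis and 10 and 2 Hsf1 genes lower.

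Camera did not call the remaining lists. Over all tested genes 1300 of 4364 were higher and 321 lower, so counts near those shares do not set a list apart. Purine and one-carbon genes rose in 12 of 20 cases (12 higher and 1 lower adjusted over the list alone), with GCV1, a glycine cleavage gene, at a log2 change of 1.49 and GLN1 at 1.14, and zinc regulon genes in 4 of 7 (4 adjusted over the list alone), among them the regulator ZAP1 and IZH1 at 1.01. Cell wall integrity genes rose in 5 of 12 cases (6 adjusted over the list alone), with PST1 at 1.81 and SED1 at 1.51, and Pho85 cyclin genes in 3 of 7 (5 adjusted over the list alone), PCL9 at 1.60, PCL1 at 1.06 and CLG1 at 0.97. Methionine genes went both ways, 5 higher and 3 lower of 17 (5 and 4 adjusted over the list alone), with the S-adenosylmethionine synthetase genes SAM1 and SAM2 at -2.04 and -1.51 and the permease gene MUP1 at 0.93. Gcn4 targets did too, 7 higher and 2 lower of 27 (7 and 2 adjusted over the list alone), with HIS4, also in the purine list, at 1.15 and ARG4 at 0.74. Among 16 glycolysis genes ENO1 (2.32) and TDH1 (2.85, or 3.59 without the shallow libraries) rose and HXK2 (-1.08) fell, the same counts holding adjusted over the list alone, and without the shallow libraries 9 rose and 1 fell. RME1 (1.55), STE5 and GPA1 rose among 10 haploid-specific genes (3 adjusted over the list alone), and NDT80 (1.36) among 3 meiosis genes (2 adjusted over the list alone). So did CLN2 (0.66) and CLN1 (1.09) among 22 G1/S genes and HHO1 (0.65) and HHT1 (0.58) among 10 histone genes, with 0 adjusted over the list alone for the last 2 lists. INM1 (1.24) rose and ITR1 (-0.71) fell among 14 phospholipid genes (1 and 0 adjusted over the list alone). AKR1 (0.67) rose and FET3 (-0.57) fell among 9 iron genes (1 and 1 adjusted over the list alone). No gene was called with limma among 3 hexose transporter and 7 a-specific genes, nor the alpha-specific STE3 (log2 change 0.59), which passed only over its list of 1. Leaving out the shallow libraries, 2 hexose transporter and 3 a-specific genes were called higher. These counts depend on the scaling as well. Median centring of the deeper libraries left 10 higher and 3 lower purine genes, 1 higher zinc gene, 2 higher Pho85 cyclin genes and 1 higher haploid-specific gene. It gave 5 higher and 2 lower cell wall integrity, 3 and 6 methionine, 5 and 5 Gcn4, 1 and 5 phospholipid, 0 and 3 iron and 0 and 3 G1/S genes. Quantile normalization left 5 higher and 1 lower purine, 4 and 0 cell wall integrity, 0 and 2 methionine, 2 and 1 Gcn4, 0 and 1 G1/S, 0 and 1 iron, 0 and 0 phospholipid, 2 and 0 glycolysis genes, 1 higher gene each in the zinc, Pho85 cyclin and haploid-specific lists and none in the meiosis list.

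**Figure D4:**
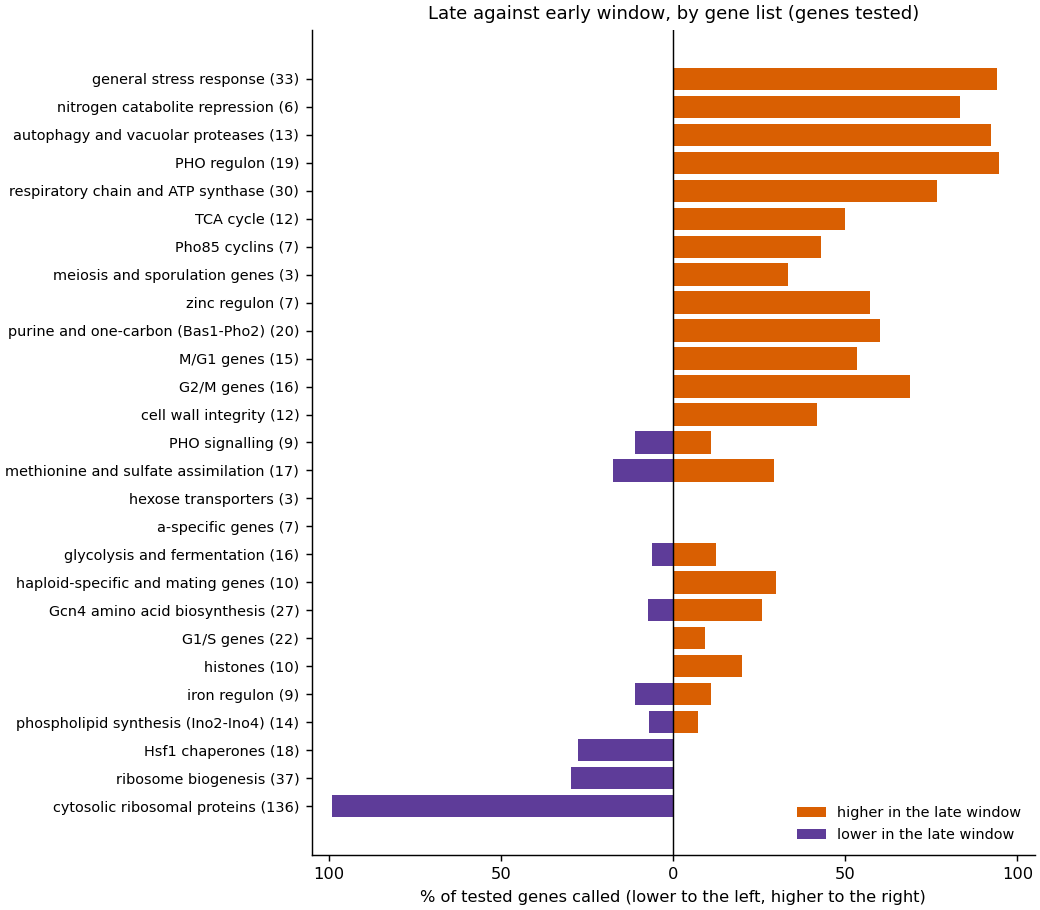
Percent of the tested genes of each list called higher (right) or lower (left) in the late window against the early window, with the number of tested genes in parentheses and lists ordered by their median log2 change. Ribosomal protein genes (135 of 136 lower) and general stress response genes (31 of 33 higher) lie at the ends, and the medians of the G1/S, histone, Gcn4, iron, a-specific and haploid-specific lists turn negative when the deeper libraries are centred on their medians.

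In all, 1621 of 4364 genes were called between the late and early windows, 1300 higher and 321 lower, of which 604 and 188 changed at least 2-fold. The median of all genes was 0.35 higher on the log2 scale in the late window, and against that median the general stress response list lay 1.72 higher, the PHO regulon 0.61 higher and the ribosomal proteins at -3.02. For the PHO regulon the median log2 change of 0.96 became 1.48 without the shallow libraries, where the median of all genes was 0.37, and 1.89 with quantile normalization. The surplus of higher calls moved with the scaling. Without the shallow libraries 1853 genes were called (1524 higher, 329 lower). Centring the deeper libraries on their medians gave 1355 (672 higher, 683 lower). Scaling them to the reads outside ribosomal protein genes gave 1368 (571 higher, 797 lower), and quantile normalization of all libraries gave 564 (301 higher, 263 lower). The last count may also reflect the shallow libraries, whose few genes that normalization spreads over the whole range. The surplus was also nearly gone with the odd-numbered time points alone, 374 genes (192 higher, 182 lower), but not with the even-numbered ones, 1105 genes (912 higher, 193 lower). Both sets required fewer listed values per window. The odd-numbered one tested 3831 genes, and its early libraries include the shallow ones at 45 and 75 min. Their part in the lost surplus was not tested. The directions of the PHO regulon, stress response, ribosomal protein, respiratory chain, autophagy and nitrogen catabolite repression medians were the same under median centring and quantile normalization. The medians of the G1/S, histone, Gcn4, iron, a-specific and haploid-specific lists became negative with median centring, and those of the G1/S, methionine, iron, haploid-specific and meiosis lists with quantile normalization. The camera direction, which is relative to all other genes, was lower although the median was positive for the PHO signalling, glycolysis, hexose transporter, G1/S, histone, methionine, iron and a-specific lists.

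A smooth curve over the 24 libraries without phosphate asked which genes changed with time at all, with no reference to 0 min. PHO89 (limma, adjusted p = 1.48e-05), PHO8, the vacuolar alkaline phosphatase gene (adjusted p = 3.45e-07), PHO5 (adjusted p = 5.12e-04), PHO81 (adjusted p = 0.00253) and PHO2 (adjusted p = 0.00338) changed, as did PHO84 (adjusted p = 0.0221) and SPL2 (adjusted p = 0.023), while PHO80 and PHO4 had adjusted p = 0.166 and 0.262. In all 1773 of 4364 genes were called, 1334 of them higher in the late than in the early window and 439 lower, and 1406 were also called between those windows. The split was 748 higher and 855 lower of 1603 without the shallow libraries and centred on their medians, and 317 and 400 of 717 with quantile normalization. With the odd-numbered time points alone 472 genes were called (255 higher, 217 lower) and with the even-numbered ones 767 (592 higher, 175 lower), each resting on 12 libraries.

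The order in which PHO regulon genes were induced was read from the time at which a fitted curve passed the midpoint on the log2 scale between its 0 min value and its maximum, for the 18 genes called in the late window. The midpoints ran from 25 min for SPL2 to 44 min for PHO81, with PHO84 at 26 min (95% bootstrap interval 23 to 43 min) and PHO5 at 33 min (27 to 146 min). No gene had a midpoint later than PHO84 with an interval of the difference above 0. The shallow libraries weighed on this result, since PHO5, PHO89 and PHM8 were higher in the 45 min library than in the deeper libraries around it. Without them, PHO5 had its midpoint at 129 min (63 to 139 min), HOR2 at 144 min, PHM8 at 148 min and GDE1 at 149 min, and these 4 were later than PHO84 at 31 min, by 98 min (12 to 111 min) for PHO5. Residuals were drawn separately for each gene although all genes come from the same libraries, so the intervals of differences are approximate. PHO84 went from 6.12 log2 RPM at 0 min to 9.13 at 15 min, so its true midpoint may lie before the fitted one. With midpoints on the linear scale the times ran from 40 min for VTC3 to 186 min for PHO81, with PHO84 at 42 min (36 to 284 min), PHO5 at 169 min (61 to 335 min) and PHO89 at 184 min (153 to 336 min), and again no gene was later than PHO84 with an interval above 0. On the log2 scale, simulated rises with a midpoint at 20 min were placed at 30.2 min on average, so midpoints before 30 min were not resolved.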

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

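Of the tests in this part, those on chance assignment for the lists, on depth for the surplus of higher calls and on the 10 read minimum were set before their results were seen, and all others were chosen only after the result was seen.

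The shares of 3 lists and the levels of the named genes were searched for a library far from the others of its window, and 19 of 138 series had one. The 5% that chance alone gives is no fair measure here. In a shallow library the 10 read minimum alone can put every listed value above those of the other libraries. Of the 19, 17 lay in shallow libraries and 2 in deeper ones. These shares are the ones the report prints, a choice made after a wider search over the shares of all lists had given 48 of 213, 45 of them in shallow libraries. The PHO regulon share stood highest at 45 min in the early window (2.78%) and at 330 min in the late window (3.26%). The ribosomal protein share stood highest at 90 min (45.4%) and at 330 min (16.1%). A deeper neighbour thinned to the 90 min depth gave 56.99% to 61.09%, so the 90 min share lay below what depth and the 10 read minimum give. Shares at 45 min (25.53% against 41.98% to 43.72%) and 75 min (30.22% against 37.85% to 38.57%) also lay below their thinned ranges. The stress response share stood highest at 45 min (1.80%) and at 210 min (7.30%). On the log2 RPM scale, the 90 min library was highest of the early window for RPL9A (12.34), RPL27A (11.98), RPS22A (11.74), RPS9A (12.18) and RPS11A (11.08). The lowest value that could be listed there, 10.978, already lay above the next highest values of RPL9A (10.685), RPL27A (10.238), RPS9A (9.567) and RPS11A (9.773). For these genes a listed value had to be the highest. The 75 min library was highest for DDR2 (7.71) and lowest for RPL33B (8.74), and the 45 min library highest for HXK1 (10.14). The 210 min library was highest of the middle window for PHO12 (14.49), and the 330 min library highest of the late window for RPS22A (10.16) and PHO11 (12.15). The lowest value that could be listed also lay above the next highest one for DDR2 (6.944 against 6.079) and HXK1 (9.074 against 7.668). The same held for PHO12 (13.671 against 12.454) and for RPS22A at 330 min (8.393 against 8.259). In deeper libraries, FMP16 was highest at 345 min (10.66) and RPL8A at 360 min (6.95). For RPL8A the lowest value that could be listed at 360 min, 5.88, also lay above the next highest one, 5.448.

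Reassigning the times at random is the check on chance. For the late window against the early window 1 of 100 assignments, the labelled one, reached 1621 genes, the highest other giving 0, and for the spline 1 of 100 reached 1773, the highest other giving 96. For the lists 5 of 100 assignments reached the 11 lists called, the highest other giving 13 and the median of the others 4, so chance is not excluded for the number of lists.

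The surplus of higher over lower calls between the late and early windows (1300 against 321, but 192 against 182 with the odd-numbered time points alone) could come from the scaling, from depth or from a real rise in most transcripts. The odd-numbered set keeps the shallow libraries at 45 and 75 min. Scaled to the reads outside ribosomal protein genes, 41.7% of calls were higher, but that rescaling moves all genes of a library alike and would lower a real rise in the same way. Scaling and a real rise therefore cannot be told apart for these calls without a spiked standard. Depth is excluded as the whole cause, since over genes complete in the deeper libraries the lowest late median lay 0.259 above the highest early one at overlapping depths. The medians ranked with depth among the 5 early libraries (rank correlation -0.900, range 0.157) and less so among the 7 late ones (-0.393), so a smaller contribution of depth stays open.

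The lower ribosomal protein share in the late window could come from depth, from the 10 read minimum, from a batch of libraries or from the cells. Random loss of reads does not give it, since early libraries thinned to the shallowest deeper late library kept at least 30.52% against a highest share of 7.522% in the deeper late libraries. Such thinning could hardly lower the share of abundant genes, so it cannot exclude other effects that go with low depth. Among the deeper libraries depths overlapped, with 340264 reads at 15 min and 645272 at 255 min, yet every early share lay above every late one. The 10 read minimum is excluded, since over genes complete in the deeper libraries the lowest deeper early share was 31.86% and the highest deeper late share 8.049%. A batch that begins at 195 min is excluded as the sole cause, since the 180 min library already stood at 14.2%, below the lowest deeper early share of 29.08% by more than their SD of 1.536. A part played by such a batch stays open, and batches beginning at other times were not tested. Among low values, the percent that were whole reads was at least 96.9 in the deeper libraries from 15 to 180 min. It was at most 96.2 in those from 195 min on, and 95.1 at 0 min. All early libraries lie before 195 min and all late ones after it, so the calls between these windows share this limit. Culture age and density moved with time without phosphate, and so would such a batch, so their parts cannot be told apart.

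Of the 5 shallow libraries 4 stand apart in ways that low depth alone does not give, and the 210 min library was not set against a thinned neighbour. In the 3 early ones PHO5 lay above the upper limit of a deeper neighbour thinned to the same depth (12.55 against 10.66 at 45 min, 10.96 against 10.13 at 75 min, 11.98 against 11.56 at 90 min), and at 330 min the ribosomal protein share of 16.1% lay above a thinned limit of 6.309%. Reads from late libraries, in shares of 56%, 18% and 22%, could bring PHO5 to its values, but the stress response share lay inside the simulated range in 0 of 3 libraries and below it in 3 of 3, which missed the limit set for this explanation. That limit was judged wrong only after the result was seen, because the ribosomal protein shares fell inside their simulated ranges in 3 of 3 and the donor profile is assumed, so the test cannot tell. The same holds at 330 min, where 26% of early reads would give a stress response share of 3.642% to 4.122% against 4.242% seen, a gap of 0.12 that is smaller than the difference between its neighbours (4.189% and 3.327%), and here too the limit set was missed and set aside afterwards.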

How the results depend on the processing

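The alternatives without the 5 shallow libraries, and the tests built on them, were chosen only after the result was seen, and the others before the data were examined. Of 69 counts under alternatives 50 stayed within 1.5 times the reported one, 15 were weaker and 4 stronger. Of 1392 results for single genes 1229 kept direction and side of the threshold, 108 were weaker, 37 stronger and 18 reversed, none of the 18 called with limma under either setting. Without quantile normalization and the odd or even time points, 970 of 1013 were the same. No paired analysis was possible because the libraries form 1 time course with no sample numbers shared between groups. The count models and the pseudocount of 10 were not run, since they apply to other units.

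Quantile normalization spreads the few listed genes of a shallow library over the whole range, by its construction. It gave 717 genes changing over time in no-phosphate medium, 564 for the late against early window, 22 for the late window against 0 min, and 0 for the early and 0 for the middle window against 0 min. Odd-numbered time points, with 12 of 24 libraries, gave 472 genes changing over time, 374 for late against early, 4 for early, 11 for middle and 453 for late against 0 min. Even-numbered ones gave 767 changing over time and 1 for early against 0 min. For the middle window against 0 min arrayWeights gave 48, and leaving out the shallow libraries 148, with unlisted values at 5 reads 127 and with complete genes only 163; the cause was not tested. With an estimated correlation 1 list was called for late against early and 1 for late against 0 min. Without the shallow libraries 4 genes followed PHO84. Leaving out each library in turn gave 1315 (without 105 min) to 1949 (without 75 min) genes changing over time, and 1137 to 1718, for the same times, for late against early.

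Reversed log2 changes under quantile normalization were, for late against early, PHO80 -0.045 and PHO4 -0.15; for early against 0 min, PHO80 -0.26, PHO86 -0.17, PPN1 -0.26 and KCS1 -0.53. For middle against 0 min they were PHO80 -0.09, PHO4 -0.32 and PHO2 -0.32, and for late against 0 min PHO80 -0.31, PHO4 -0.59 and PHO2 -0.21. With median centring of the deeper libraries they were KCS1 -0.076 (early), PHO4 -0.22 (middle) and PHO4 -0.22 (late). With arrayWeights PHO4 stood at -0.027 (middle), with even-numbered time points at -0.079 (late), and with odd-numbered ones PHO2 at 0.077 (early). The cause was not tested. Of the 4364 tested genes 4338 lack a value somewhere, and the 210 min library alone lists only 29 genes.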

Other observations

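The tests between neighbouring windows were chosen only after the result was seen, and so were the genes named here.

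Between the early and middle windows 309 of 4364 genes changed with limma, 170 higher and 139 lower, and between the middle and late windows 242, 170 higher and 72 lower. SOL4 (log2 change 2.48), GPG1 (2.28), GLC3 (2.26), CYC7 (2.05) and CMC4 (2.03) rose from the early to the middle window. GRE1 (3.43), SIP18 (3.18), CTT1 (2.93) and HSP26 (2.79) rose from the middle to the late window. Without the shallow libraries the counts were 520 (406 higher, 114 lower) and 407 (276 higher, 131 lower). Of 136 ribosomal protein genes 92 were lower across the first of these steps and 57 across the second, but without the shallow libraries 62 and 101, so which step held more calls depends on those libraries. The share of reads of these genes, given above, had reached its late level within the middle window. RPL8A, for example, stood at 8.98 log2 RPM at 150 min, 5.05 at 240 min and 5.15 at 255 min. The middle mean thus covers libraries before and after the fall, and calls in the second step do not show a further fall after 240 min. Of 37 ribosome biogenesis genes 9 fell in the first step (8 without the shallow libraries), with a median log2 change of -0.83 against 0.17 for all genes. In the second step none of them was called with limma, and their median was 0.29 against 0.19 for all genes, or 0.17 against 0.17 without the shallow libraries.

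The spline called 367 genes that the late against early contrast did not. GIT1, a glycerophosphoinositol transporter gene of the PHO regulon that was listed too rarely to be tested, stood at 1.60 log2 RPM at 0 min. It was unlisted throughout the early window and stood at 2.95 at 150 min and 6.81 at 360 min.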
